A study of Mus musculus with 10 samples.

How the data were processed

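Brain RNA of C57BL/6 mice was measured on 10 Affymetrix MOE430A arrays, 3 for each labelled sex at 1 week and 2 for each at 8 weeks. The deposited values were an intensity per probe set on a linear scale, 1 column per array. The software and settings with which the authors summarised the probes were not given in the sources used here, and no detection calls were used here. Groups of age and labelled sex were taken from the labels. The arrays were not on a common scale: the highest trimmed mean was 2.3 times the lowest, with 2% trimmed from each tail. The number of arrays limits the precision. Correlations of log2 values ran from 0.973 to 0.981 within groups and from 0.933 to 0.951 between ages.

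The model, the tests, the gene lists, the rule for named genes and all alternatives but those named last were chosen before the data were examined. So was the rule for scaling, which called for quantile normalization where trimmed means lay more than 5% apart, and quantile normalization was therefore used. The table held 22690 probe sets, of which 64 were array controls and 22626 were kept. A pseudocount of 24, the 20th percentile of all deposited values, was added before taking log2. Probe sets with a mean log2 value under the 40th percentile were left out, which left 13576, the dimmest with a mean normalized intensity of 73.9. A symbol was given by the annotation for 20380 probe sets, several symbols for 691 and no symbol for 1555. A gene was represented by its brightest probe set with a single symbol, giving 8148 genes after the filter. Of 1455 genes past the threshold for age with more than 1 probe set, 34 had a probe set called in the opposite direction.

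Linear models were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), with 1 coefficient per group of age and labelled sex. Contrasts were 8 weeks minus 1 week over both labels and within each, male minus female over both ages and at each age, and the age by sex interaction. All p-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The 33 gene lists held 892 genes and were tested with camera at a preset correlation of 0.01, then with an estimated correlation and with fry. Lists with fewer than 5 measured members were counted and not tested. Named genes were the 12 largest rises and the 12 largest falls for age among genes whose ages did not overlap, and from each list up to 4 members passing in the main direction and up to 2 in the other. A fixed panel of receptor, myelin, glial and sex chromosome genes and any gene passing for sex or the interaction were named too. A single measure per array was compared between ages with an exact permutation test. Alternatives were other pseudocounts, deposited values without normalization, median scaling, other filters, each array left out, a replicate block, an intensity trend, array weights, fits of the compared groups alone, other list tests and a 2-fold minimum. After the data were seen, age alone as the model, the same without arrays whose sex markers did not match their label, scaling to spike-in controls, and the X-linked list without Xist were added. The pipeline was tested on simulated data of 22626 probe sets with 200 changed. For age, log2 changes of 0.5, 1 and 2 were recovered in 54.5%, 92.5% and 97% of cases, for sex over both ages in 48%, 96.5% and 98.5%, and for sex at 8 weeks in 0%, 71% and 96%. In simulated lists, 1 shifted list was called and 0 of the others, among 30 lists. Simulated genes varied independently, whereas the cerebellar list, for 1, had an estimated correlation of 0.80. The simulation therefore cannot show how often the preset correlation gives false calls in the real lists.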

Results

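Gene expression was measured in brain of C57BL/6 mice, an inbred laboratory strain, at 1 week and at 8 weeks of age, in samples labelled female and male. The labels state that age and sex were the factors of interest. Each sample was hybridised to 1 Affymetrix MOE430A array, a short-oligonucleotide array that reads each transcript with 1 or more probe sets. The 10 arrays comprised 3 labelled female and 3 labelled male at 1 week, and 2 labelled female and 2 labelled male at 8 weeks. The labels number the brains within each group and do not state that they came from separate animals, so the p-values below measure the spread between these samples. Precision was limited by the number of arrays. Deposited intensities differed in overall brightness, with trimmed means from 138 to 318. At 8 weeks the trimmed mean was 290.3 ± 27.9 (SD, n = 4) and at 1 week 201 ± 35.5 (SD, n = 6), a difference past the spread between arrays (two-sided exact permutation test, p = 0.00476, adjusted p = 0.0238 over 5 measures). The adjusted p was above the threshold for the other measures. The 3' to 5' signal ratio of the beta-actin control was 1.11 ± 0.0402 against 1.03 ± 0.0506 (exact permutation p = 0.0381, adjusted p = 0.0952). The Gapdh control ratio was 0.793 ± 0.017 against 0.822 ± 0.0726 (exact permutation p = 0.476). Spike-in controls averaged 789 ± 64.1 against 618 ± 149 (exact permutation p = 0.0667), and the 3' probe set of 18S ribosomal RNA 1719 ± 1571 against 3207 ± 1719 (exact permutation p = 0.21).

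Transcripts of the sex chromosomes followed the sex labels at 8 weeks and went against them in 4 of the 6 arrays at 1 week. Xist, the X-linked RNA that silences an X chromosome in female cells, read 1676 and 1405 in the arrays labelled female at 8 weeks and 131 and 134 in those labelled male. Eif2s3y, a Y-linked translation factor gene, read 1.04 and 6.09 in the former and 70.7 and 57.4 in the latter. At 1 week, replicates 1 and 2 labelled female had Xist at 163 and 164 with Eif2s3y at 75.9 and 147. Replicates 2 and 3 labelled male had Xist at 1664 and 1422 with Eif2s3y at 1.19 and 1.14. Replicate 1 labelled male had the pattern of its label, with Xist at 293 and Eif2s3y at 70.7. Replicate 3 labelled female carried both transcripts, Xist at 866 and Eif2s3y at 53.9. A single probe set of each of the Y-linked genes Kdm5d, a histone demethylase gene, and Uty followed Eif2s3y. That of Kdm5d read 82.3 and 82.0 in replicates 1 and 2 labelled female at 1 week and 29.5 and 15.1 in replicates 2 and 3 labelled male, and that of Uty 55.6 and 73.1 against 31.4 and 21.5. The other Kdm5d probe sets read 48.2 and 48.8 against 31.9 and 42.7, and 16.8 and 15.9 against 35.5 and 30.8, the last in the other direction. It read 36.9 and 8.83 in the arrays labelled male at 8 weeks and 6.92 and 5.55 in those labelled female. Another Uty probe set read 69.8 and 52.7 against 46.9 and 31.8 at 1 week. The same 4 arrays stood on the other side on the deposited scale. Arrays are therefore named below by their label, and at 1 week a label cannot be read as the sex of the brain.

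**Figure D1:**
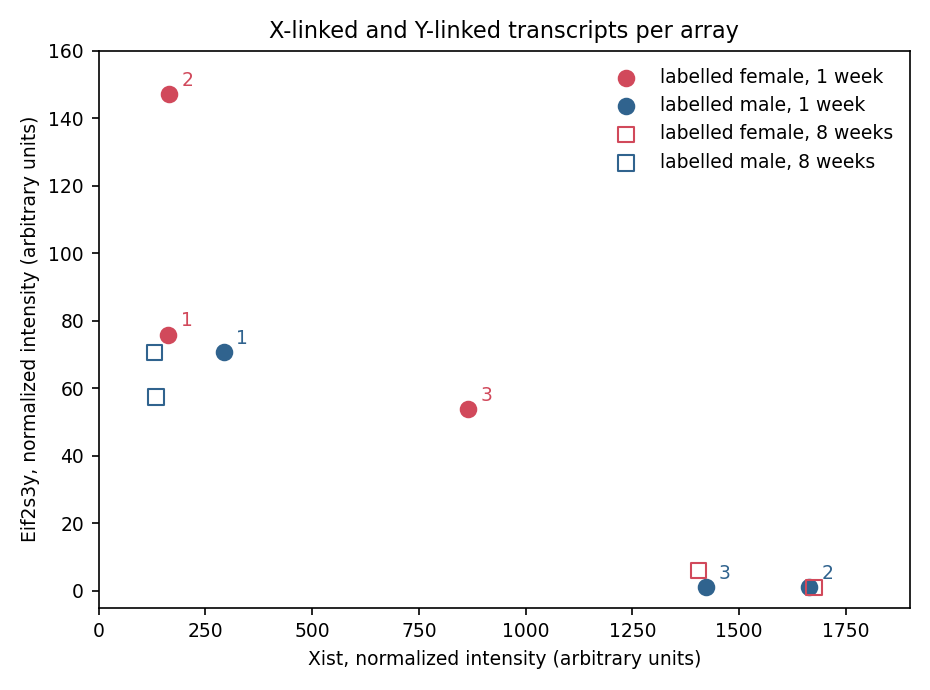
Normalized intensity of Eif2s3y (Y-linked, vertical axis) against Xist (X-linked, horizontal axis), 1 point per array, coloured by labelled sex, filled circles for 1 week with their replicate numbers and open squares for 8 weeks. Replicates 1 and 2 labelled female at 1 week lie with the arrays labelled male at 8 weeks, replicates 2 and 3 labelled male lie with those labelled female, and replicate 3 labelled female lies between, at 866 for Xist and 53.9 for Eif2s3y.

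The first comparison asked how brain expression differed between 1 and 8 weeks, with all groups in the fit. Most measured genes of growing neurons, of cell division and of extracellular matrix were lower at 8 weeks, and most of those of myelin, synapses and cerebellar neurons were higher. As sets these lists passed with a preset correlation between genes and not with an estimated one (adjusted p from 0.0704 to 0.372 over 8 lists). The estimate ran from 0.038 for presynaptic to 0.80 for cerebellar genes, but was 0.00344 for GABA and glycine genes, below the preset 0.01. It was also below 0.01 for the precursor, progenitor, channel, perineuronal net, glycolysis and antigen presentation lists treated below. In those lists and the GABA list, correlation between genes does not account for the lost call. Of the lists called for age with the preset correlation, 0 lost their call with fry, which does not set a list against the other genes. Levels are given as normalized intensity, mean ± SD over 4 arrays at 8 weeks and 6 at 1 week, and changes as log2 at 8 weeks minus 1 week ± SE. Among genes whose arrays of the 2 ages did not overlap, the steepest falls included Col1a1, the main chain of type I collagen (-3.69 ± 0.59), Dpysl3 (-3.45 ± 0.11) and Dcx (-3.37 ± 0.18). The steepest rises included the pituitary hormone gene Prl (4.15 ± 0.60), the myelin gene Mobp (3.72 ± 0.76) and Gabra6, a GABA receptor subunit of cerebellar granule cells (3.61 ± 0.48). Within 8 weeks Prl ran from 76.6 in replicate 2 labelled male to 4909 in replicate 1 labelled female. Rises outside every list included Gprc5b, an orphan receptor gene (2.90 ± 0.12), Aldh1a1, a retinaldehyde dehydrogenase gene (2.89 ± 0.23), Csrp1 (2.76 ± 0.16) and Kalrn, a regulator of dendritic spines (2.70 ± 0.17). Of 13576 probe sets tested with limma, 2993 were higher and 3253 lower at 8 weeks at an adjusted p under 0.05, and 450 and 393 of these changed at least 2-fold. By gene, 1783 of 8148 were higher and 1956 lower. The 2 ages did not overlap in 2925 genes, 35.9% of those tested, where chance gives 0.952%. Without normalization between arrays the median change of all probe sets was 0.47 and the split was 8673 higher to 629 lower, so directions here are relative to the whole distribution of intensities. Scaled to the spike-in controls, an alternative added after seeing the data, the split was 3156 to 1386, with a median change of 0.13. With age alone in the model and without the 4 arrays whose sex markers opposed their label, 2069 were higher and 1973 lower. Without replicate 3 labelled female at 1 week as well, 1 array of 1 week was left, replicate 1 labelled male. Calls in that setting cannot show whether an age effect holds. Without these 5 arrays the Prl call was lost, at a change of 4.35.

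**Figure D2:**
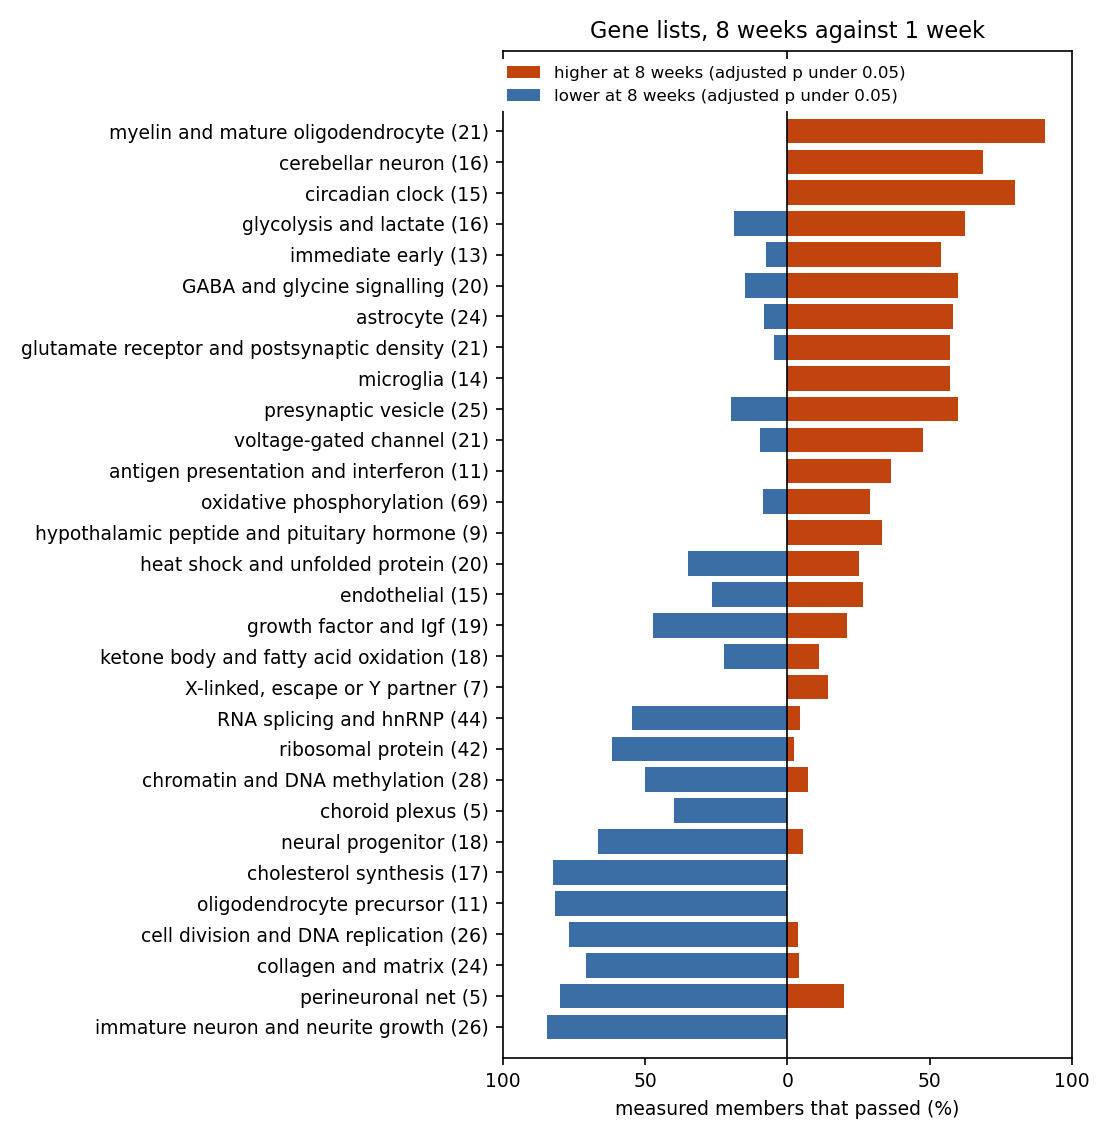
Share of the measured members of each gene list (number in parentheses) that passed an adjusted p under 0.05 for 8 weeks against 1 week, in percent, with members lower at 8 weeks drawn to the left and members higher to the right. Lists are ordered by their median log2 change, with myelin at the top, where 19 of 21 members were higher, and immature neurons at the bottom, where 22 of 26 were lower.

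Genes of immature neurons and neurite growth fell in 22 of 26 measured members and 4 did not pass, and 22 fell when adjusted over the list alone. Dcx, a microtubule protein of migrating neurons, went from 2076 ± 219.8 to 187 ± 68.0, and Dpysl3, a cytoskeletal regulator of growth cones, from 4411 ± 472 to 382 ± 53.7. Its relative Dpysl5 fell by 3.27 on the log2 scale and the surface protein gene Cd24a went from 1698 ± 295 to 149.9 ± 19.5. As a set these genes were lower than the rest (camera adjusted p = 4.83e-13, and adjusted p = 0.0986 with an estimated correlation). St8sia2, the enzyme that adds polysialic acid to the adhesion molecule Ncam1, went from 754 ± 84.9 to 109 ± 8.83, Rac3, a small GTPase, from 1797 ± 262 to 241 ± 13.9, and Marcksl1 from 4262 ± 227 to 599 ± 194. Cell division and DNA replication genes fell in 20 of 26 members and 1 rose (camera adjusted p = 5.90e-07, and adjusted p = 0.148 with an estimated correlation), and 1 rose and 21 fell when adjusted over the list alone. Top2a, the topoisomerase of dividing cells, went from 230.3 ± 64.3 to 29.9 ± 6.41, Mcm6, part of the replicative helicase, from 197 ± 39.0 to 17.5 ± 3.87, and the mitotic kinase gene Cdk1 from 286 ± 84.6 to 22.6 ± 18.4. The member that rose, Anln, encodes a cytokinesis protein that is also made by myelinating oligodendrocytes, and changed by 1.77 ± 0.16. Neural progenitor genes fell in 12 of 18 members and 1 rose, though on the deposited scale their median turned above 0, at 0.0133, below the 0.47 of all probe sets. The set was lower than the rest (camera adjusted p = 0.00246, and adjusted p = 0.0787 with an estimated correlation), and 1 rose and 12 fell when adjusted over the list alone. Fabp7, the fatty acid binding protein of radial glia, went from 3514 ± 260.3 to 448 ± 44.4, and Mycn, a growth-promoting transcription factor gene, from 305 ± 69.6 to 122 ± 13.7. Prom1, a membrane protein gene, was the member that rose (0.72 ± 0.15).

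**Figure D3:**
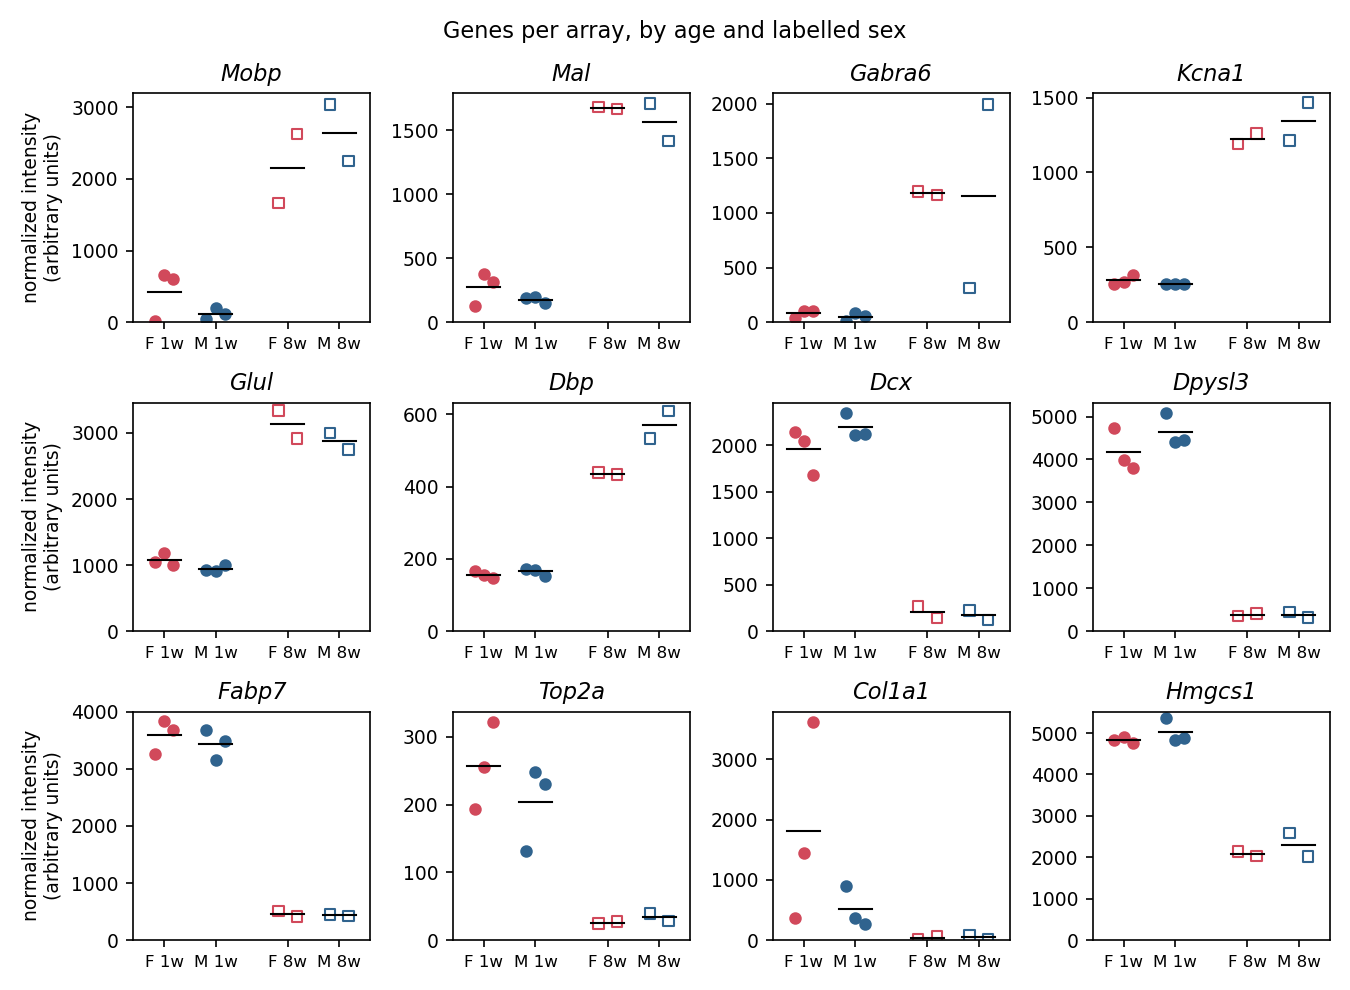
Normalized intensity of 12 genes in each array, by labelled sex (F, M) and age (1w, 8w), with filled circles for 1 week, open squares for 8 weeks and a horizontal line at the group mean. Mobp, Mal, Gabra6, Kcna1, Glul and Dbp were higher and Dcx, Dpysl3, Fabp7, Top2a, Col1a1 and Hmgcs1 lower in the 4 arrays of 8 weeks than in the 6 arrays of 1 week, without overlap.

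Myelin and mature oligodendrocyte genes rose in 19 of 21 measured members and 0 fell, with 20 rising when adjusted over the list alone (camera adjusted p = 7.20e-10, and adjusted p = 0.124 with an estimated correlation). Mobp, a structural protein of compact myelin, was 2395 ± 585 at 8 weeks and 272 ± 284 at 1 week, and Mal, a myelin membrane proteolipid, 1616 ± 135 at 8 weeks and 224 ± 99.1 at 1 week. Cryab, a small heat shock protein of oligodendrocytes, changed by 2.72 ± 0.17 and Plekhb1 by 2.56 ± 0.13. Mbp, the myelin basic protein gene, was 5703 ± 473 at 8 weeks and 3381 ± 1842 at 1 week and did not pass (log2 0.95 ± 0.39, adjusted p = 0.0703). Its arrays at 1 week ran from 1234 in replicate 1 labelled female to 5618 in replicate 2 of that group, and it passed without replicate 1 labelled female at a smaller change (0.59 ± 0.17, adjusted p = 0.0197), without replicate 2 (1.13 ± 0.38, adjusted p = 0.0391) and without replicate 3 (1.12 ± 0.38, adjusted p = 0.0384), with a range of 0.00109 to 0.161 over its alternatives. Cerebellar neuron genes at 1 week had list scores of -1.14 and -1.23 in replicate 1 of either label, against -0.29 and -0.0511 in replicates 2 and 3 labelled female. In replicates 2 and 3 labelled male the cerebellar scores were -0.36 and -0.50, and the myelin scores -0.72 and -0.83. Oligodendrocyte precursor genes fell in 9 of 11 members and 0 rose, also when adjusted over the list alone (camera adjusted p = 1.44e-04, and adjusted p = 0.0704 with an estimated correlation). Pdgfra, the growth factor receptor of precursors, went from 455 ± 70.3 to 153 ± 22.9, and the matrix proteoglycan gene Vcan from 318 ± 35.6 to 82.4 ± 4.96. Astrocyte genes rose in 14 of 24 members and 2 fell, with the same counts when adjusted over the list alone (camera adjusted p = 4.31e-05, and adjusted p = 0.124 with an estimated correlation). Glul, the glutamine synthetase gene, was 3002 ± 247 at 8 weeks and 1008 ± 97.4 at 1 week, and the gap junction gene Gjb6 changed by 2.07 ± 0.12. The members that fell were Aldh1l1, a folate enzyme gene (-0.80 ± 0.13), and Sox9, a glial transcription factor gene (-0.65 ± 0.09). Gfap, the astrocyte intermediate filament gene, was 922 ± 187 at 8 weeks and 920.5 ± 279 at 1 week and did not pass (adjusted p = 0.906). On the deposited scale, where the median of all probe sets was 0.47, Gfap passed (0.58 ± 0.22, limma adjusted p = 0.0272). Microglia genes rose in 8 of 14 members and 0 fell, with 8 rising when adjusted over the list alone (camera adjusted p = 0.00675, and adjusted p = 0.343 with an estimated correlation). Among them Ctss, a lysosomal protease gene, changed by 1.00 ± 0.10 and P2ry12, a receptor of resting microglia, by 0.59 ± 0.09. On the deposited scale calls were lost for Aldh1l1 (-0.26 ± 0.17, adjusted p = 0.169, 1.12e-04 to 0.169 over its alternatives) and Sox9 (-0.27 ± 0.15, adjusted p = 0.106, 7.54e-05 to 0.106 over its alternatives). Without the 5 arrays whose sex markers did not match their label, with 1 array of 1 week left, P2ry12 lost its call at a change of 0.42.

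**Figure D4:**
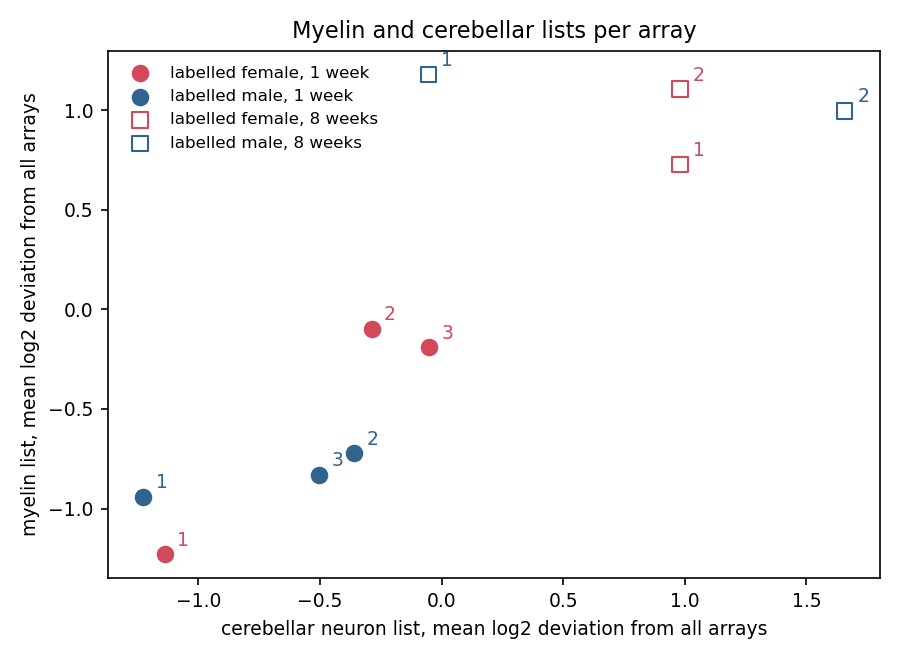
Mean log2 deviation of the myelin list (vertical axis) against that of the cerebellar neuron list (horizontal axis), 1 point per array with its replicate number, coloured by labelled sex, filled circles for 1 week and open squares for 8 weeks. The 6 arrays of 1 week spread from -1.23 to -0.0975 in the myelin list, and replicate 1 labelled male at 8 weeks lies apart from the others of its age in the cerebellar list, at -0.0537 against 0.98 to 1.66.

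Genes of synaptic transmission were mostly higher at 8 weeks. Presynaptic vesicle genes rose in 15 of 25 members and 5 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.0068, and adjusted p = 0.123 with an estimated correlation). Vamp1, a vesicle fusion protein gene, was 1795 ± 423 at 8 weeks and 378 ± 211 at 1 week, Cplx1 5203 ± 617 at 8 weeks and 2214 ± 295 at 1 week and Snap25 4182 ± 291 at 8 weeks and 2086 ± 192 at 1 week. Doc2a, a calcium sensor gene, was among the members that fell (-0.76 ± 0.14). Glutamate receptor and postsynaptic density genes rose in 12 of 21 members and 1 fell, again the same when adjusted over the list alone (camera adjusted p = 0.00397, and adjusted p = 0.343 with an estimated correlation). Grin2c, an NMDA receptor subunit prominent in cerebellum, changed by 2.55 ± 0.30, Camk2a, a postsynaptic kinase gene, by 2.13 ± 0.21 and Dlg4, the scaffold PSD-95, by 0.99 ± 0.11. The member that fell was Cnih2, an AMPA receptor auxiliary subunit (-0.91 ± 0.12). Grin2b, an NMDA receptor subunit of young neurons, read 82.6 ± 24.2 at 8 weeks and 86.1 ± 24.7 at 1 week and did not pass (adjusted p = 0.877). GABA and glycine signalling genes rose in 12 of 20 members and 3 fell, and 13 rose and 3 fell when adjusted over the list alone (camera adjusted p = 8.63e-04, and adjusted p = 0.0704 with an estimated correlation). Pvalb, the calcium buffer of fast-spiking interneurons and Purkinje cells, was 1861 ± 738 at 8 weeks and 167 ± 82.3 at 1 week, and Gabrd, an extrasynaptic receptor subunit, changed by 2.21 ± 0.21. Lhx6, a transcription factor of migrating interneurons, fell (-0.81 ± 0.19). The chloride exporter Slc12a5 and the chloride importer Slc12a2 both rose, by 0.74 ± 0.08 and 0.96 ± 0.15. Gabra2 did not pass (log2 0.17 ± 0.15, adjusted p = 0.372). On the deposited scale, where the median of all probe sets was 0.47, Gabra2 passed (0.66 ± 0.13, limma adjusted p = 3.09e-04). Its change was -0.36 without the 5 doubted arrays, with 1 array of 1 week left. Voltage-gated channel genes rose in 10 of 21 members and 2 fell, and 11 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.00246, and adjusted p = 0.0787 with an estimated correlation). The potassium channel gene Kcna1 was 1282 ± 126 at 8 weeks and 266 ± 24.0 at 1 week, and its auxiliary subunits Kcnab2 and Kcnab1 changed by 1.96 ± 0.10 and 1.56 ± 0.11. Scn3b, a sodium channel beta subunit, fell (-1.40 ± 0.14). Cerebellar neuron genes rose in 11 of 16 members and 0 fell, with 12 rising when adjusted over the list alone (camera adjusted p = 1.48e-04, and adjusted p = 0.372 with an estimated correlation). Gabra6 was 1166 ± 687 at 8 weeks and 65.3 ± 37.5 at 1 week and ranged from 310.4 in replicate 1 labelled male to 1993 in replicate 2 labelled male at 8 weeks. Cbln3, a granule cell synaptic organiser, changed by 2.75 ± 0.37. Of 5 perineuronal net genes measured, out of 9 listed, 4 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.0143, and adjusted p = 0.116 with an estimated correlation). The 5 were Tnc, Ncan, Bcan, Vcan, also in the precursor list, and Hapln2, also in the myelin list. Acan, Hapln1, Hapln4 and Tnr were not measured after the filter, so these counts say nothing on them. Tnc, a matrix glycoprotein gene, fell (-1.95 ± 0.12), as did the proteoglycan gene Ncan (-1.25 ± 0.09), while Hapln2, a link protein of nodes of Ranvier, rose (1.53 ± 0.21). Doc2a and Lhx6 lost their calls on the deposited scale, with Doc2a (-0.31 ± 0.15, adjusted p = 0.0792, 4.28e-04 to 0.0792 over its alternatives) and Lhx6 (-0.36 ± 0.17, adjusted p = 0.0697, 6.79e-04 to 0.0697 over its alternatives).

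Most matrix genes of blood vessels and meninges were lower at 8 weeks. Collagen, extracellular matrix and mural or meningeal genes fell in 17 of 24 members and 1 rose, and 2 rose and 17 fell when adjusted over the list alone (camera adjusted p = 2.11e-06, and adjusted p = 0.217 with an estimated correlation). Col4a1, a basement membrane collagen, went from 927 ± 60.9 to 222 ± 25.9 and Col3a1 from 529.9 ± 259.7 to 63.7 ± 8.97. Col1a1 went from 1161 ± 1283 to 42.1 ± 31.3, and at 1 week it ran from 266 in replicate 3 labelled male to 3613 in replicate 3 labelled female. Endothelial genes went both ways, 4 of 15 rising and 4 falling, also when adjusted over the list alone, and the list did not pass as a set (camera adjusted p = 0.789). The members that rose were the transporter genes Slco1a4 (1.42 ± 0.15), Abcb1a (1.01 ± 0.08) and Slc2a1, which carries glucose (0.84 ± 0.08), and the tight junction gene Ocln (0.34 ± 0.09). Kdr, the receptor for vascular endothelial growth factor, fell (-0.69 ± 0.08), as did Cldn5, another tight junction gene (-0.60 ± 0.08). Of 5 choroid plexus genes 2 fell and 0 rose, also when adjusted over the list alone, and the list median of -0.30 turned to 0.0461 on the deposited scale. The set did not pass (camera adjusted p = 0.273). Igfbp2, a binding protein for insulin-like growth factors, went from 980.4 ± 157 to 465 ± 49.2. Without replicate 2 labelled female at 8 weeks the choroid plexus list passed (adjusted p = 0.0392), with a range of 0.0346 to 0.897 over its alternatives. Calls lost on the deposited scale were those of Kdr (-0.21 ± 0.14, adjusted p = 0.183, 4.82e-05 to 0.183 over its alternatives) and Cldn5 (-0.0565 ± 0.14, adjusted p = 0.72, 1.17e-04 to 0.72 over its alternatives). The Ocln call was lost without the 4 arrays whose sex markers opposed their label (0.36 ± 0.16, adjusted p = 0.137). Without 5 arrays, with 1 array of 1 week left, it was also lost, at a change of 0.46.

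More glycolytic genes rose than fell, and most genes of cholesterol synthesis fell. Among those of ribosomes, splicing and chromatin more fell than rose, though on the deposited scale their medians turned above 0, at 0.18, 0.25 and 0.21, all below the 0.47 of all probe sets. As sets these 5 lists did not pass with an estimated correlation (adjusted p from 0.0704 to 0.123). Glycolysis and lactate genes rose in 10 of 16 members and 3 fell, and 11 rose and 3 fell when adjusted over the list alone (camera adjusted p = 5.37e-04, and adjusted p = 0.0704 with an estimated correlation). Aldoc, the aldolase of brain, was 5681 ± 591 at 8 weeks and 1968 ± 248 at 1 week, Eno2, the neuronal enolase gene, 2488 ± 133 at 8 weeks and 1111 ± 53.0 at 1 week and Pkm 3150.4 ± 229.5 at 8 weeks and 1653 ± 161 at 1 week. Ldha, a lactate dehydrogenase subunit gene, fell (-0.75 ± 0.09), as did Slc16a1, a lactate and ketone body transporter gene (-0.76 ± 0.08). Ketone body and fatty acid oxidation genes rose in 2 of 18 members and fell in 4, also when adjusted over the list alone, without a call for the set (camera adjusted p = 0.485). Those that fell included the ketone enzymes Bdh1 (-0.96 ± 0.07), Acat1 (-0.79 ± 0.08) and Oxct1 (-0.64 ± 0.12), and Hadhb, an enzyme of fatty acid oxidation, rose (0.74 ± 0.07). Oxidative phosphorylation genes rose in 20 of 69 members and 6 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.0143, and adjusted p = 0.564 with an estimated correlation). Sdha, a subunit of complex II, changed by 0.71 ± 0.07 and Cox8a, a subunit of cytochrome c oxidase, by 0.44 ± 0.07. The set no longer passed without replicate 1 labelled female at 1 week (adjusted p = 0.0664) or without replicate 2 labelled female at 8 weeks (adjusted p = 0.0558), with a range of 0.00498 to 0.564 over its alternatives. Cholesterol synthesis genes fell in 14 of 17 members and 0 rose, and 1 rose and 14 fell when adjusted over the list alone (camera adjusted p = 1.02e-05, and adjusted p = 0.116 with an estimated correlation). Hmgcs1, the synthase that supplies the pathway, went from 4928 ± 213 to 2192 ± 269, Fdps from 1367 ± 79.8 to 511 ± 50.6 and Sqle from 1188 ± 92.8 to 478 ± 43.3. Ribosomal protein genes fell in 26 of 42 members and 1 rose, and 1 rose and 29 fell when adjusted over the list alone (camera adjusted p = 9.29e-07, and adjusted p = 0.116 with an estimated correlation). Rplp0 went from 3328 ± 123 to 1534 ± 55.4 and Rpsa from 4301 ± 216 to 2229.7 ± 195. RNA splicing genes fell in 24 of 44 members and 2 rose, and 3 rose and 27 fell when adjusted over the list alone (camera adjusted p = 1.60e-04, and adjusted p = 0.115 with an estimated correlation). Ptbp1, a splicing repressor of progenitors, went from 505 ± 44.9 to 247 ± 15.6. Chromatin and DNA methylation genes fell in 14 of 28 members and 2 rose, with the same counts when adjusted over the list alone (camera adjusted p = 0.00246, and adjusted p = 0.123 with an estimated correlation). The DNA methyltransferase gene Dnmt3a went from 877 ± 34.6 to 307 ± 31.5 and Hmgb3 from 1091 ± 68.1 to 283 ± 53.0, while Ezh1, a histone methyltransferase gene, rose (0.83 ± 0.08). Idh1, the cytosolic isocitrate dehydrogenase gene, lay in no list and went from 1403 ± 107 to 243 ± 73.2. Calls were lost on the deposited scale for Ldha (-0.23 ± 0.13, adjusted p = 0.13, 1.65e-05 to 0.13 over its alternatives) and Slc16a1 (-0.22 ± 0.15, adjusted p = 0.201, 2.08e-05 to 0.201 over its alternatives). The same held for Acat1 (-0.24 ± 0.15, adjusted p = 0.176, 4.01e-06 to 0.176 over its alternatives) and Oxct1 (-0.11 ± 0.17, adjusted p = 0.563, 8.81e-04 to 0.563 over its alternatives). Oxct1 also lost its call without the 4 arrays whose sex markers opposed their label (-0.49 ± 0.18, adjusted p = 0.077). Without 5 arrays, with 1 array of 1 week left, it was also lost, at a change of -0.30.

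Genes of the circadian clock were higher at 8 weeks in 12 of 15 members and lower in 0, and 14 rose and 0 fell when adjusted over the list alone. This was the list whose call held with an estimated correlation (camera adjusted p = 4.36e-07, and adjusted p = 0.033 with an estimated correlation), out of 30 tested, of which 13 were higher and 10 lower with the preset correlation. Dbp, a clock output transcription factor gene, was 504 ± 84.0 at 8 weeks and 161 ± 10.3 at 1 week, Hlf 647 ± 69.4 at 8 weeks and 222 ± 28.9 at 1 week and Bhlhe40, a clock repressor gene, 411 ± 49.3 at 8 weeks and 104 ± 26.3 at 1 week. The labels used here give no time of day for the samples. Immediate early genes, which neurons transcribe within minutes of activity, rose in 7 of 13 members and 1 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.0068, and adjusted p = 0.118 with an estimated correlation). Egr1 was 1861 ± 195 at 8 weeks and 661 ± 161 at 1 week and Egr3 293 ± 39.2 at 8 weeks and 151 ± 46.8 at 1 week. Antigen presentation and interferon genes rose in 4 of 11 members and 0 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.0267, and adjusted p = 0.118 with an estimated correlation). H2-D1, a class I histocompatibility gene, changed by 0.59 ± 0.14 and B2m, its partner chain, by 0.51 ± 0.11. This list lost its call on the deposited scale (adjusted p = 0.0659) and with the filter at the 60th percentile (adjusted p = 0.0909), with a range of 6.59e-04 to 0.118 over its alternatives. With age alone in the model and without the 5 arrays of 1 week whose sex markers did not match their label, 1 array of 1 week was left. The microglia, presynaptic, glutamate, immediate early, antigen presentation and oxidative phosphorylation lists lost their calls there. With 1 array of 1 week this cannot be told from the loss of arrays. Over its alternatives with camera or fry, adjusted p ran from 5.63e-04 to 0.343 for microglia, 8.42e-05 to 0.123 for presynaptic and 7.67e-04 to 0.343 for glutamate genes. Egr3 also lost its call in the setting with 1 array of 1 week, at a change of 0.58. H2-D1 lost it without the 4 arrays whose sex markers opposed their label (0.56 ± 0.19, adjusted p = 0.0639, 3.70e-05 to 0.0639 over its alternatives).

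Age effects were then compared between the labelled sexes. Dpysl3 changed by -3.36 ± 0.15 on the log2 scale among arrays labelled female and by -3.54 ± 0.15 among arrays labelled male. Mobp rose by 3.12 ± 1.07 and 4.33 ± 1.07, and Mal by 2.64 ± 0.34 and 2.99 ± 0.34. By the interaction test the mean change of the myelin list was higher by 0.50 under the male label (camera adjusted p = 0.00113, and adjusted p = 0.703 with an estimated correlation, 1.59e-14 to 0.725 over its alternatives). This call was lost without replicate 1 labelled female at 8 weeks, at 0.31 (adjusted p = 0.182). The mean was 0.91 (adjusted p = 1.59e-14) without replicate 1 labelled female at 1 week, 0.29 (adjusted p = 0.03) without replicate 2 of that group. Among arrays labelled female 1957 probe sets were higher and 2198 lower at 8 weeks, and among arrays labelled male 2106 and 2249. Over 3216 genes that passed in at least 1 labelled sex, the changes correlated across genes, which are not independent replicates, with r = 0.925 and rho = 0.897. Their slope was 1.04 and 97.1% had the same sign. Across all genes, not chosen by passing, r was 0.866. Genes passing in both with the same sign numbered 1835, 861 higher and 974 lower, where independent lists would share 177 and 216, and 4 passed with opposite signs. The age by sex interaction called 0 probe sets with limma (lowest adjusted p = 0.236), with 759 at an unadjusted p under 0.05 where 679 were due by chance. The lowest p was that of Gtf2ird1, a transcription factor gene chosen after its values were seen, with 295 at 1 week and 352 at 8 weeks under the female label and 420.1 and 171 under the male label. Its age effect differed by -1.44 ± 0.20 between the labels, and it passed without replicate 1 labelled female at 1 week (adjusted p = 0.0449). Without replicate 1 labelled male at 1 week a probe set without a gene name passed, and without replicate 2 labelled female at 8 weeks 2 genes did, Ecrg4 and Ybx3. Xist differed by -4.86 ± 1.08 (adjusted p = 0.857), with means at 1 week of 398 under the female label and 1126 under the male label. Since 4 arrays of 1 week had sex markers against their label, the interaction and the agreement above compare labels and not sexes. They cannot show whether age effects are alike in the sexes. Counts for a labelled sex rested on 2 arrays at 8 weeks: without replicate 1 labelled female at 8 weeks 1148 probe sets were higher and 1356 lower, without replicate 2 1153 and 1433, and among arrays labelled male, without replicate 2 at 8 weeks, 1240 and 1315.

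The last comparison set arrays labelled male against arrays labelled female. At 8 weeks, where markers and labels matched, Xist averaged 132 in arrays labelled male and 1540.4 in arrays labelled female, and Eif2s3y, which lay below the intensity filter, 64.0 and 3.57. The X-linked genes Eif2s3x and Kdm6a, which have Y-linked partners, read 917 and 153 in arrays labelled male at 8 weeks against 1252 and 229.5 in those labelled female, Ddx3x 1179.6 against 1389, Kdm5c 119 against 128, Usp9x 495 against 502 and Zfx 159.5 against 165. Of these, the probe sets tested did not pass in the fit of all groups, where the log2 difference of Xist at 8 weeks was -3.32 ± 0.84 (adjusted p = 1). In a fit of the 4 arrays of 8 weeks alone, 3 probe sets passed (limma, 347 at an unadjusted p under 0.05). They were the 2 Xist probe sets that passed the filter, by -3.32 ± 0.14 (adjusted p = 0.00242) and -4.37 ± 0.21 (adjusted p = 0.00391), and a probe set without a gene name in the annotation used here, chosen after its values were seen, by 3.73 ± 0.13 (adjusted p = 0.0014). In the fit of all groups limma called 0 probe sets over both ages, 0 at 1 week and 0 at 8 weeks. At an unadjusted p under 0.05 there were 469, 1150 and 345, where 679 were due by chance. At 1 week, and so over both ages, these counts compare labels and not sexes. Arrays of 1 week also entered the spread used at 8 weeks. The SD of Xist was 406 and 732 in arrays labelled female and male at 1 week, and 191 and 2.41 at 8 weeks. Counts of 0 therefore cannot be read as no difference between the sexes. The lowest p over both ages was that of Alas2, the enzyme of haem synthesis in red cell precursors, at 294 in arrays labelled female and 103 in arrays labelled male at 1 week (adjusted p = 0.159 at 1 week). Slc25a37, the mitochondrial iron importer of red cell precursors, was 148 against 60.9 at 1 week (adjusted p = 0.14). Slc25a37 was chosen after its values were seen. Leaving out 1 array called 2 genes at 1 week without replicate 3 labelled male, Safb2 and Inpp5k. At 8 weeks it called 2 probe sets without replicate 1 labelled female, Hamp and another unnamed probe set, 2 without replicate 2 labelled female, Ecrg4 and Ybx3, and 1 without replicate 1 labelled male of 1 week, the unnamed probe set that passed among the arrays of 8 weeks alone.

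No gene list passed for the labelled sexes over both ages (lowest camera adjusted p = 0.0653, and lowest adjusted p = 0.798 with an estimated correlation, over 30 lists). Leaving out 1 array gave calls: 0 higher and 4 lower in arrays labelled male without replicate 1 labelled female at 1 week, and 0 and 1 without replicate 3 of that group. At 8 weeks there were 0 and 3 without replicate 1 labelled female, 1 and 1 without replicate 2, 1 and 1 without replicate 1 labelled male, and 3 and 4 without replicate 2. At 1 week myelin genes were lower in arrays labelled male, with a mean log2 difference of -0.33 over 21 members, of which 0 passed singly, over all genes or when adjusted over the list alone (camera adjusted p = 0.0066, and adjusted p = 0.746 with an estimated correlation). The mean was -0.74 (adjusted p = 3.29e-14) without replicate 1 labelled female at 1 week, -0.12 (adjusted p = 0.297) without replicate 2 labelled female at 1 week and -0.17 (adjusted p = 0.224) without replicate 3 labelled female at 1 week. It was -0.67 (adjusted p = 0.0198) on the deposited scale and -0.16 (adjusted p = 6.55e-09) scaled to spike-in controls. Its adjusted p ran from 3.29e-14 to 0.746 over its alternatives, and the cerebellar scores of these arrays correlated with the myelin scores at r = 0.837 (exact permutation p = 0.0514). At 8 weeks the X-linked genes with reported escape from inactivation or a Y-linked partner were lower in arrays labelled male, with a mean log2 difference of -0.66 (camera adjusted p = 6.07e-05, and adjusted p = 0.352 with an estimated correlation), with 0 passing over all genes and 3 when adjusted over the list alone. Without Xist, an alternative added after seeing the data, the mean was -0.22 over 6 members (camera adjusted p = 0.00281, and adjusted p = 0.5 with an estimated correlation). Immediate early genes were lower, with a mean of -0.22 (camera adjusted p = 0.00162, and adjusted p = 0.352 with an estimated correlation). So were immature neuron genes, with -0.11 (camera adjusted p = 0.022, and adjusted p = 0.861 with an estimated correlation), and hypothalamic and pituitary genes, with -0.47 (camera adjusted p = 0.022, and adjusted p = 0.666 with an estimated correlation). Choroid plexus genes were higher, with a mean of 0.41 (camera adjusted p = 0.0142, and adjusted p = 0.666 with an estimated correlation). So were oxidative phosphorylation genes, with 0.0602 (camera adjusted p = 0.0378, and adjusted p = 0.861 with an estimated correlation). In the 5 lists after the X-linked one 0 members passed singly, over all genes or when adjusted over the list alone, and 0 of the 6 calls at 8 weeks held with an estimated correlation. The X-linked and immediate early lists passed whichever array was left out, with adjusted p from 2.28e-06 to 0.789 and 3.36e-05 to 0.789 over their alternatives with camera or fry, and the immediate early mean was -0.45 (adjusted p = 3.36e-05) on the deposited scale. With fry 0 of these calls at either age held. The other 4 depended on single arrays or settings. The choroid plexus mean was -0.0146 (adjusted p = 0.864) without replicate 1 labelled female at 8 weeks and 0.82 (adjusted p = 1.77e-07) without replicate 2 labelled female at 8 weeks, and 0.20 (adjusted p = 2.47e-05) on the deposited scale (1.77e-07 to 0.899 over its alternatives). That of hypothalamic and pituitary genes was 0.36 (adjusted p = 0.617) without replicate 1 labelled female at 8 weeks, -0.74 (adjusted p = 6.21e-04) without replicate 2 labelled female at 8 weeks, -0.41 (adjusted p = 0.139) without replicate 1 labelled male at 8 weeks and -0.13 (adjusted p = 0.263) without replicate 2 labelled male at 8 weeks, and -0.19 (adjusted p = 0.141) with a smaller pseudocount (2.59e-04 to 0.899). That of immature neuron genes was -0.00268 (adjusted p = 0.864) without replicate 1 labelled female at 8 weeks, -0.21 (adjusted p = 6.21e-04) without replicate 2 labelled female at 8 weeks, -0.18 (adjusted p = 0.00332) without replicate 1 labelled male at 8 weeks and -0.0324 (adjusted p = 0.543) without replicate 2 labelled male at 8 weeks. It was -0.31 (adjusted p = 0.0615) on the deposited scale, -0.0436 (adjusted p = 0.0598) with median scaling and -0.13 (adjusted p = 0.0603) scaled to spike-in controls (6.21e-04 to 0.899). For oxidative phosphorylation it was 0.0559 (adjusted p = 0.0579) without replicate 3 labelled female at 1 week, 0.0557 (adjusted p = 0.0712) without replicate 3 labelled male at 1 week and 0.0134 (adjusted p = 0.864) without replicate 1 labelled female at 8 weeks. The same list gave 0.11 (adjusted p = 0.00208) without replicate 2 labelled female at 8 weeks, 0.0611 (adjusted p = 0.11) without replicate 1 labelled male at 8 weeks and 0.0506 (adjusted p = 0.273) without replicate 2 labelled male at 8 weeks. By setting it was 0.0611 (adjusted p = 0.0554) with a smaller pseudocount, -0.094 (adjusted p = 3.64e-05) on the deposited scale, 0.17 (adjusted p = 3.82e-07) with median scaling and 0.0944 (adjusted p = 2.28e-06) scaled to spike-in controls (3.82e-07 to 0.899). For all lists in this paragraph, camera set a list against the other genes on the same scale and did not test its mean against 0. Where a scale shifts all genes between the labels, the sign of a mean need not be the direction of the call.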

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

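Of the tests in this part, those of the sex markers, of the myelin list and of the splits for sex were chosen after the results were seen, while the splits for age, the search for arrays far from the others and the interaction were planned. Of the 100 splits of the arrays that keep the group sizes within each label, 1, the real one, gave as many as 6246 probe sets for age, with at most 2 in the others. This share is under 0.05 and argues against a chance division of the arrays. Trimmed means also separated the ages, from 255 to 318 at 8 weeks and from 138 to 236 at 1 week. The splits alone therefore cannot tell age from other differences between these arrays. For labelled sex over both ages the real count was 0, which any split reaches. The 60 of 60 splits within the ages that did, with at most 2 in the others, say nothing on chance. At 1 week the real count was also 0, reached by all 10 splits with at most 2, and 10 splits are too few for a share under 0.05.

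At 1 week 4 arrays, 2 of each label, had both Xist and Eif2s3y on the side of the other sex. Against transcripts that are not yet expressed by sex at this age stood an Xist intensity of 1664 in replicate 2 labelled male, above the 1405 of replicate 2 labelled female at 8 weeks. Against an effect of the normalization between arrays stood the same count of 4 on the deposited scale. An exchange of sex labels at 1 week may account for these 4 arrays, since partners out of place were found under both labels. Alas2 (234 to 363 under the female label, 86.0 to 124 under the male), Slc25a37 (117 to 179.8 under the female label, 52.5 to 68.8 under the male) and the globin probe set of Hba-a1 and Hba-a2 (784 to 1119 under the female label, 178 to 321 under the male) did not overlap between the labels at 1 week. They were chosen after their values were seen, and Alas2 and Slc25a37 had the lowest p of all genes between these labels. The separation of Alas2 and Slc25a37 therefore follows from that choice, and no share due by chance was computed. Whether samples, RNA or records were exchanged stays open.

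Replicate 3 labelled female at 1 week carried both Xist and Y-linked transcripts. Its Xist intensity lay 0.521 of the way from the level of arrays labelled male at 8 weeks to that of arrays labelled female, and the mean of Eif2s3y, Kdm5d and Uty lay 0.606 of the way in the other direction. Both positions lay between the bounds of 0.2 and 0.8, so RNA of both sexes in 1 array may account for them. Eif2s3y alone lay 0.832 of the way, outside the bounds, and the mean of 6 probe sets of these genes 0.605. No biological explanation was tested.

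Myelin list scores ran from -1.23 to -0.0975 over the 6 arrays of 1 week and from 0.73 to 1.18 over the 4 of 8 weeks. A candidate explanation is the share of cerebellum or hindbrain in the sample: the myelin score correlated with the cerebellar score (r = 0.837, exact permutation p = 0.0514, adjusted 0.103 over 4 relations, rho = 0.886, p = 0.0333, r = 0.776 without replicate 1 of either label). The cerebellar score also correlated with the cell division score (r = 0.963, exact permutation p = 0.00278, adjusted 0.0111, rho = 0.943, p = 0.0167, r = 0.818 without the same arrays). Older pups would show less cell division with more myelin, and r was 0.753 (exact permutation p = 0.0944, adjusted 0.126, rho = 0.771, p = 0.103, r = 0.669 without replicates 2 and 3 labelled female), and array brightness gave r = 0.561 (exact permutation p = 0.244, adjusted 0.244, rho = 0.543, p = 0.297, r = 0.446 without replicate 1 labelled male and replicate 3 labelled female). Of the 16 cerebellar genes measured, 3 were in other lists (Gabra6, Pvalb and Grin2c), and Pvalb ran from 62.8 to 270.1 and Gabra6 from 12.4 to 106 at 1 week, and with 6 arrays the share of cerebellum, the age of the pups and the brightness cannot be told apart.

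In 29 of 390 comparisons of the arrays of 1 age, for named genes, list scores and array measures, 1 array stood far from the others by Dixon's gap ratio, where 19.5 were due by chance. Among named genes there were 8 of 160 (8 due by chance) at 1 week, as many as chance gives, and 17 of 160 (8 due by chance) at 8 weeks, and among list scores 3 of 30 (1.5 due by chance) and 1 of 30 (1.5 due by chance). Replicate 1 labelled male at 1 week was higher than the others of its age in Col8a1 (126 against 83.7 to 97.6), Hmgcs1 (5353 against 4764 to 4909) and choroid plexus list score (0.36 against 0.0551 to 0.12) and lower in B2m (692 against 907 to 1034) and Oxct1 (1912 against 2475 to 2641). Replicate 3 labelled female at 1 week was higher than the others of its age in Col3a1 (1044 against 327 to 488), Kcna1 (313 against 252 to 269.8) and oligodendrocyte precursor list score (0.42 against 0.27 to 0.32). Replicate 2 labelled female at 1 week was higher than the others of its age in Eno2 (1211 against 1065 to 1115) and Hspa4 (379 against 280.1 to 291). Replicate 1 labelled female at 1 week was lower than the others of its age in neural progenitor list score (0.032 against 0.19 to 0.26). Replicate 2 labelled female at 8 weeks was higher than the others of its age in Alas2 (136 against 75.9 to 82.5) and Hdac5 (982 against 855 to 874) and lower in Slco1a4 (454 against 575 to 604). Replicate 1 labelled female at 8 weeks was higher than the others of its age in Cdk1 (50.1 against 13.2 to 13.5) and lower in Atp5g1 (1030.4 against 1337 to 1373), Cryab (524 against 832 to 876), Hadhb (775 against 847 to 859), Herpud1 (434 against 678 to 702), Snrpe (449.9 against 541 to 553), Vamp1 (1161 against 1986 to 2034) and oxidative phosphorylation list score (-0.0153 against 0.0779 to 0.0956). Replicate 2 labelled male at 8 weeks was lower than the others of its age in Cnih2 (695 against 811 to 818), Col4a1 (183 against 229 to 238), Mal (1415 against 1664 to 1706), Scn3b (297 against 469.9 to 512) and St8sia2 (95.5 against 112 to 114). Replicate 1 labelled male at 8 weeks was higher than the others of its age in Rrm2 (64.3 against 41.0 to 43.2) and lower in Snap25 (3752 against 4261 to 4358).

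The age effect differed between the labels in 7 gene lists by the interaction test, given as the mean log2 difference, male minus female. It was higher in arrays labelled male for myelin (0.50, camera adjusted p = 0.00113, and adjusted p = 0.703 with an estimated correlation), oxidative phosphorylation (0.0826, camera adjusted p = 0.0467, and adjusted p = 0.851 with an estimated correlation) and ketone body and fatty acid oxidation (0.19, camera adjusted p = 0.0162, and adjusted p = 0.703 with an estimated correlation). It was lower for immature neurons (-0.17, camera adjusted p = 0.0254, and adjusted p = 0.726 with an estimated correlation) and glutamate receptors (-0.25, camera adjusted p = 0.00671, and adjusted p = 0.703 with an estimated correlation). It was also lower for immediate early genes (-0.34, camera adjusted p = 0.00627, and adjusted p = 0.685 with an estimated correlation) and X-linked genes (-0.93, camera adjusted p = 0.00113, and adjusted p = 0.685 with an estimated correlation). With an estimated correlation 0 of the 7 held, and the mean for the X-linked list includes Xist, which at 1 week went against the labels of 4 arrays. Without Xist the mean was -0.28 over 6 members (camera adjusted p = 0.0162, and adjusted p = 0.703 with an estimated correlation). These 6 were compared across the same labels, so leaving out Xist does not remove the mismatch at 1 week. The X-linked and immediate early calls held whichever array was left out, with an immediate early mean of -0.55 (adjusted p = 2.06e-04) scaled to spike-in controls. With fry 0 of the 7 held. For myelin the mean was 0.91 (adjusted p = 1.59e-14) without replicate 1 labelled female at 1 week, 0.29 (adjusted p = 0.03) without replicate 2 labelled female at 1 week and 0.31 (adjusted p = 0.182) without replicate 1 labelled female at 8 weeks (1.59e-14 to 0.725 over its alternatives). For glutamate receptors the mean was -0.17 (adjusted p = 0.0866) without replicate 3 labelled female at 1 week, -0.16 (adjusted p = 0.182) without replicate 1 labelled female at 8 weeks and -0.22 (adjusted p = 0.0582) without replicate 1 labelled male at 8 weeks. It was -0.0984 (adjusted p = 0.00174) on the deposited scale, -0.12 (adjusted p = 0.00454) with median scaling and -0.41 (adjusted p = 0.00741) scaled to spike-in controls (5.37e-05 to 0.708). For immature neurons it was -0.0922 (adjusted p = 0.364) without replicate 3 labelled female at 1 week, -0.13 (adjusted p = 0.112) without replicate 1 labelled male at 1 week, -0.0653 (adjusted p = 0.553) without replicate 1 labelled female at 8 weeks, -0.28 (adjusted p = 0.0011) without replicate 2 labelled female at 8 weeks and -0.0943 (adjusted p = 0.307) without replicate 2 labelled male at 8 weeks. It was -0.00297 (adjusted p = 0.101) on the deposited scale, -0.0232 (adjusted p = 0.119) with median scaling and -0.36 (adjusted p = 0.0273) scaled to spike-in controls (0.0011 to 0.759). For ketone body and fatty acid oxidation it was 0.14 (adjusted p = 0.176) without replicate 3 labelled female at 1 week, 0.16 (adjusted p = 0.0893) without replicate 3 labelled male at 1 week, 0.10 (adjusted p = 0.337) without replicate 1 labelled female at 8 weeks and 0.16 (adjusted p = 0.0531) without replicate 1 labelled male at 8 weeks. It was 0.34 (adjusted p = 0.00608) on the deposited scale, 0.32 (adjusted p = 0.00422) with median scaling and -7.16e-04 (adjusted p = 0.009) scaled to spike-in controls (0.0011 to 0.708). For oxidative phosphorylation it was 0.13 (adjusted p = 8.12e-04) without replicate 1 labelled female at 1 week, 0.0596 (adjusted p = 0.273) without replicate 2 labelled female at 1 week, 0.0494 (adjusted p = 0.409) without replicate 3 labelled female at 1 week and 0.0622 (adjusted p = 0.231) without replicate 3 labelled male at 1 week. The same list gave 0.0366 (adjusted p = 0.578) without replicate 1 labelled female at 8 weeks, 0.13 (adjusted p = 0.00323) without replicate 2 labelled female at 8 weeks, 0.0811 (adjusted p = 0.0693) without replicate 1 labelled male at 8 weeks and 0.0706 (adjusted p = 0.222) without replicate 2 labelled male at 8 weeks. By setting it was 0.0839 (adjusted p = 0.0539) with a smaller pseudocount, 0.32 (adjusted p = 2.90e-06) on the deposited scale, 0.30 (adjusted p = 2.87e-08) with median scaling and -0.0381 (adjusted p = 3.39e-04) scaled to spike-in controls (2.87e-08 to 0.851). Camera set each list against the other genes on the same scale and did not test these means against 0. On another scale the sign of a mean therefore need not be the direction of the call.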

How the results depend on the processing

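Scaling to the spike-in controls, age alone as the model and leaving out the doubted arrays or Xist were chosen after seeing the data, and the other alternatives were planned. Of 160 named genes 150 passed for age, and 117 of these kept their call and direction under each of the 19 alternatives fixed in advance for genes in which they were tested. On the deposited scale 26 lost the call or its sign, with age alone 3, and scaled to spike-in controls 10. Without the 4 arrays whose sex markers opposed their label 18 of 144 lost it. With 5 arrays left out, 1 array of 1 week remained, which cannot show whether a call holds. Without at least 1 array 13 lost it: Atp5g1, Btg2, Cacna1b, Cartpt, Cd74, Gabra3, Kdm6a, Mgp, Prpf8, Slc17a6, Srsf5, Syt2 and Vim. Dim genes lie near the pseudocount of 24, so their log2 changes are understated.

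On the deposited scale, where the median of all probe sets was 0.47, 58.1% of the 6235 age calls still tested were kept, 28 were called the other way, and 8673 probe sets were higher and 629 lower at 8 weeks. Under that scale the counts were 5377 and 476 for the female label, 6924 and 355 for the male label, 2 for sex over both ages, 7 at 1 week, 1 at 8 weeks and 1 for the interaction, with 1 list higher in arrays labelled male. The 7 were Slc25a37, Srrm1, Safb2, Rsad2, Alas2, a probe set of the alpha globin genes Hba-a1 and Hba-a2, and an unnamed probe set. The 2 were Alas2 and the globin probe set, and the others were the unnamed one. Among named genes that passed on at least 1 of the 2 scales, the sign of the log2 age change reversed there for Bcan (0.12), Atp5e (0.19), Atp5g1 (0.26), Btg2 (0.13), Calr (0.00241), Eif2s3x (0.42), Usp9x (0.48), Hspe1 (0.0713) and Pdia3 (0.10), where relative to the median of all probe sets the values were -0.35, -0.28, -0.21, -0.34, -0.47, -0.0453, 0.00729, -0.40 and -0.37. Among those that passed on neither it turned for Grin2b (0.36), Xist (0.37), Kdm5c (0.25) and Zfx (0.30). Scaled to spike-in controls, 67.8% of the 6242 age calls still tested were kept and 1386 probe sets were lower, 615 for the female label, with 1360 higher and 1061 lower for the male label. That scaling gave 1 for sex (the globin probe set), 4 at 1 week (the globin probe set, Rpl37a, Safb2 and Alas2), 1 at 8 weeks (the unnamed probe set) and 2 for the interaction (the unnamed probe set and Xist), with 2 lists higher and 4 lower in arrays labelled male. Median scaling gave 1 at 1 week (Safb2). The cause was not tested.

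With at least a 2-fold change, fewer probe sets by construction, there were 450 and 393 for age, 419 and 444 for the female label and 491 and 414 for the male label. Without the 4 arrays whose sex markers opposed their label, fewer samples, 3786 of 6246 age calls were kept, 62.1% of the 6096 still tested, and 1973 were lower. Without 5 arrays 3106 were kept, 51.6% of the 6015 still tested, with 1975 higher, 1747 lower and 7 lists higher. The fit without 5 arrays had 1 array of 1 week left. Its counts and share therefore cannot show how far the age calls depend on the doubted arrays. Fitting only the groups compared gave 3 at 8 weeks. An estimated correlation left 1 list higher and 0 lower for age. Lists that differed between the labels were 1 higher and 2 lower with the mean of the probe sets of a gene, 2 lower with no filter and 1 lower with the filter at the 60th percentile. Leaving out each array in turn, age counts ran from 2480 to 2936 higher and 2729 to 3126 lower, 1148 to 1990 and 1356 to 2195 for the female label and 1240 to 2215 and 1315 to 2324 for the male label. An arm left with 1 array was assumed to vary like the other groups. The same settings gave 0 to 0 for sex, 0 to 2 at 1 week, 0 to 2 at 8 weeks and 0 to 2 for the interaction, with 12 to 13 lists higher and 10 to 11 lower for age, and 0 to 3 higher and 0 to 4 lower in arrays labelled male. Choroid plexus genes passed under the deposited scale (adjusted p = 0.0346, 0.0346 to 0.897 over the alternatives). Same-numbered arrays of different groups correlated at r from -0.0251 to 0.193 over 13 pairs after group means were removed, 5 of them over 0.1, and 8 of 10 arrays correlated best with an array of their own number. Removing group means makes the 2 arrays of a group at 8 weeks mirror each other, so the pairs are not independent. No chance share was computed, so this count cannot decide whether the number marks a batch. With the number as a block 2847 probe sets were higher and 3054 lower for age, and 0 passed for sex, sex at 1 week, sex at 8 weeks and the interaction with limma. Mbp passed for age under the block (1.16 ± 0.35, adjusted p = 0.0265, 0.00109 to 0.161 over its alternatives), and the interaction in oxidative phosphorylation genes did not (adjusted p = 0.055, 2.87e-08 to 0.851 over its alternatives).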

Other observations

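The list tests in this part were planned, and the values per array were looked at after the results were seen. Growth factor genes went both ways, with 4 of 19 measured members rising and 9 falling at 8 weeks, also when adjusted over the list alone. The set did not pass (camera adjusted p = 0.351, 0.00842 to 0.517 over its alternatives). Fgf1, a fibroblast growth factor gene, was 739.5 ± 103 at 8 weeks and 126 ± 38.6 at 1 week, and Ptn, the pleiotrophin gene, 909 ± 77.4 at 8 weeks and 2185 ± 140.5 at 1 week. Igf2, an insulin-like growth factor gene of fetal tissue and meninges, changed by -1.12 ± 0.13 and Igfbp4 by -0.98 ± 0.12. Heat shock and unfolded protein genes rose in 5 of 20 members and fell in 7, also when adjusted over the list alone, without a call for the set (camera adjusted p = 0.924). Herpud1, a gene of protein degradation at the endoplasmic reticulum, rose (1.17 ± 0.17) and the mitochondrial chaperonin gene Hspe1 fell (-0.48 ± 0.10). The Hspe1 call was lost on the deposited scale (0.0713 ± 0.14, adjusted p = 0.656, 0.0012 to 0.656 over its alternatives) and scaled to spike-in controls (-0.30 ± 0.14, adjusted p = 0.114). Without the 5 arrays whose sex markers did not match their label, with 1 array of 1 week left, it was also lost, at -0.46.

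Of 9 hypothalamic peptide and pituitary hormone genes 3 rose and 0 fell, and 2 rose and 0 fell when adjusted over the list alone, without a call for the set (camera adjusted p = 0.485). Those that rose were Prl, the prolactin gene (4.15 ± 0.60), Gh, the growth hormone gene (4.04 ± 1.01), and Cartpt, a feeding-related peptide gene (0.29 ± 0.11). The Cartpt call was lost without any 1 array other than replicate 3 labelled female at 1 week (adjusted p = 0.0605 to 0.121 in these 9 settings, 3.90e-04 to 0.576 over its alternatives). Prl read 4909 and 495 in the arrays labelled female at 8 weeks and 556 and 76.6 in those labelled male. Gh read 8002, 576, 3659 and 605 in the same order, and at 1 week 574, 1473 and 19.1 under the female label and 12.1, 11.4 and 13.7 under the male label. Of 4 sex hormone receptor and steroid enzyme genes 1 rose and 0 fell, also when adjusted over the list alone, and the list was too small to test. The gene that rose, Hsd11b1, encodes an enzyme that regenerates glucocorticoid (1.14 ± 0.11). Of 3 erythroid genes 1 fell and 0 rose, also when adjusted over the list alone, in a list too small to test. Alas2 was 92.9 ± 29.2 at 8 weeks and 199 ± 113 at 1 week. Its age call, -0.80 ± 0.16, was lost with age alone in the model (-0.80 ± 0.34, adjusted p = 0.0696). It was also lost without the 4 arrays whose sex markers opposed their label (-0.79 ± 0.27, adjusted p = 0.0606). Without 5 arrays, with 1 array of 1 week left, the call was lost and the change of Alas2 was -0.38. At 1 week it read 285, 363 and 234 in the arrays labelled female and 124, 99.2 and 86.0 in those labelled male.

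The unnamed probe set called among the arrays of 8 weeks alone read 247, 337 and 142 in replicates 1 to 3 labelled female at 1 week and 191, 16.2 and 1.61 in those labelled male. At 8 weeks it read 0.705 and 0.805 under the female label and 323 and 287 under the male label. Of the Y-linked genes named in the annotation 0 passed the intensity filter. The unnamed probe set, which passed it, was high in the arrays where Eif2s3y was high and low in the others. A Y-linked transcript without a name here may therefore have passed. Of 7 X-linked genes 1 rose with age over all genes and 0 when adjusted over the list alone, and the set did not pass (camera adjusted p = 0.924). The gene that rose was Kdm6a, a histone demethylase gene (0.30 ± 0.10), a call lost without replicate 1 labelled female at 1 week (adjusted p = 0.0669), replicate 2 labelled female at 1 week (adjusted p = 0.0591), replicate 1 labelled male at 1 week (adjusted p = 0.0692), replicate 2 labelled male at 1 week (adjusted p = 0.0683), replicate 1 labelled female at 8 weeks (adjusted p = 0.119), replicate 2 labelled female at 8 weeks (adjusted p = 0.051) and replicate 2 labelled male at 8 weeks (adjusted p = 0.144), with a range of 4.97e-04 to 0.313 over its alternatives.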
